A study of Arabidopsis thaliana with 6 samples.

How the data were processed

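Polyadenylated RNA of whole Arabidopsis thaliana plants was sequenced from 2 genotypes, the Col wild type (WT) and the gemin2 mutant, with 3 libraries each. Per the labels, the plants were 9 days old and had grown at 22 °C under constant illumination, and the libraries came from an Illumina TruSeq kit that starts from random-primed, polyA-selected RNA. The protocol in the labels names no strand-marking step, so overlapping genes on opposite strands are treated as sharing reads. The 6 libraries were grouped by genotype alone. The columns of the deposited tables carry the letters A, B and C, which no label ties to the replicate numbers 1 to 3 of the samples, so each column was used as a library of its genotype with no number of its own. All columns of sample values were used (0 left out). Nothing in the labels says that the libraries of a genotype came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

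The authors deposited raw read counts per gene, per annotated alternative splicing bin and per intron, as whole numbers that were not normalised. Per the submitters' processing notes, TopHat2 2.0.9, R 3.0.2, edgeR 3.4.2 and the genome build TAIR10 were used. The counting tool, the rule for reads that map to several places, and whether a gene's count includes the reads of its introns and splicing bins are not given in the sources used here. For a few introns, such as LpxC3 I003, the reads exceed those of the gene, so intron reads were not all counted there. The gene table has 33602 loci, of which 25897 have at least 1 read. The splicing table has 7973 bins in 5074 loci, each typed by the authors as intron retention (IR), exon skipping (ES), alternative 5' site, alternative 3' site or several of these (multiple). The intron table used here is held in part: it ends at 65535 introns in 12018 loci, on chromosomes 1 (32245 introns), 2 (18204) and 3 (15086), so introns of chromosomes 4 and 5 and part of chromosome 3 were not analysed here. The authors also deposited tables of their own comparison. These hold log2 fold changes and log2 splicing index ratios of the mutant over WT and false discovery rates (adjusted p-values), per the file headers. Values from them are named as the authors'.

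Names came from the deposited tables for 9911 loci and from the RefSeq annotation of TAIR10.1 for 1104 more. Coordinates are those of the deposited tables on TAIR10. At these coordinates the TAIR10.1 sequence had the GT-AG ends of an intron for 64457 of 65405 introns with a strand (98.6%). Of the introns, 968 overlap another annotated gene, as do 135 splicing bins. The counts of 158 loci with at least 60 reads were identical to those of another locus in all libraries.

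Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its default minimum of 10, TMM normalisation, quasi-likelihood F test, mutant against WT, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error (SE) of a log2 fold change is its size over the square root of F. Levels in CPM (edgeR's counts scaled by library size) use the TMM library sizes. Introns and splicing bins were tested the same way with the log of the same gene's count in the same library as offset, so that a change is relative to the gene. Their genes had to pass the gene filter with a mean of at least 20 reads, and the introns or bins a minimum count of 5. Their levels are given as reads per 100 reads of the gene. The median intron shift rests on the log2 ratio of intron to gene reads (0.5 added to both) of each tested intron in each library. Ratios were centred per intron on the mean of all 6 libraries rather than of WT alone, so that the exact permutation test treats both genotypes alike. The median over tested introns was then taken in each library. Shares and overlaps were tested with binomial and Fisher's exact tests, two-sided.

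Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the 16 lists. The lists are circadian clock, Sm, LSm and snRNP proteins, SR splicing regulators, flowering time, cold response, heat response, abscisic acid and drought response, salicylic acid and pathogen defence, jasmonate, light signalling, photosynthesis, root organ markers, dividing cell markers, seed storage and oil body, anthocyanin and flavonoid, and aliphatic glucosinolate. The lists, the tests and the rule for naming genes were fixed before the data were examined. Named genes are GEMIN2, then the 10 higher and 10 lower genes with the largest absolute log2 fold change among those past the threshold that had a mean log2 CPM of at least 1, a symbol, and all libraries of 1 genotype above all of the other, and from each list the 2 members highest and the 2 lowest by log2 fold change over SE among those past the threshold (where none passed, the 2 with the smallest p). Named introns and bins are the 10 higher and 5 lower with the smallest p that had a symbol, and those past the threshold in the clock, SR and Sm lists, at most 10 per list. Members of a list are named by the symbol the tables give their locus, or by the locus code where they give none. Some further members of the anthocyanin and flavonoid, cold response and photosynthesis lists are named outside this rule. Other genes are named only where stated.

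A ratio with 1 to 3 reads in a group is the ratio of pooled reads with a 95% exact counting interval. With 0 reads in a group the fold is a lower bound from a floor of 3 reads over the group. Such intervals and floors cover counting error only. Gene reads ranged from 14049163 to 17217408 per library. No pair of libraries of 1 genotype was within counting noise, as the same library deposited again would be (chi-square per degree of freedom 2.54 to 4.64). This does not show whether they came from separate plants or extracts. On simulated counts with the means and library sizes of these data (and, for introns and bins, the observed gene counts and a fixed dispersion), 82.1% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 4.66% of the calls were false (20641 genes tested). For introns (4938 tested) the recovered shares were 4.48%, 26.9% and 75.8%, with 1.39% false calls. For splicing bins (4649 tested) they were 14.9%, 64.2% and 83.3%, with 1.82% false calls. A simulated list of 20 genes shifted by 0.5 on the log2 scale was called, and 0 of 20 unshifted lists were. The simulated genes were drawn independently of each other. The simulation thus does not show how often the preset correlation gives false calls for lists of correlated genes.

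Alternatives included RLE normalisation, DESeq2 1.42.0, limma-voom, edgeR's exact test, a robust fit, other filters and thresholds, intron and bin tests without the gene offset, leaving out overlapping features, an additive term for the column letter, and leaving out each library. Taking the reads of its bin E005 off the gene count of U1-70K, leaving out loci with identical counts, and rRNA and organelle loci, and using the column letter in place of the replicate number were chosen after seeing the data. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.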

Results

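Whole-plant transcriptomes of 9-day-old Arabidopsis thaliana were profiled by RNA-seq of polyadenylated RNA in WT plants and in plants mutant for gemin2, 3 libraries per genotype, all grown at 22 °C under constant light. GEMIN2 is a core protein of the SMN complex, which loads Sm proteins onto the small nuclear RNAs of the spliceosome. The libraries held 14051562, 16732098 and 14049163 gene reads in WT A, B and C, and 15467372, 17217408 and 16543178 in gemin2 A, B and C. The introns in the table used here cover chromosomes 1 and 2 and part of 3. Their reads came to 1.13%, 1.07% and 1.04% of the gene reads of all chromosomes in WT A, B and C. In gemin2 A, B and C the shares were 0.998%, 1.03% and 1.03%, lower in each mutant library than in any WT library. The gene reads include those of rRNA and organelle loci, whose shares were higher in each mutant library. This lowers the intron share in the mutant, and the order of the libraries without those loci was not tested. The comparison between genotypes asked how the mutation altered transcript levels and splicing. Values below are means ± SD of the 3 libraries of a genotype unless another error is named, and fold changes are on the log2 scale, gemin2 over WT.

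GEMIN2 itself (AT1G54380, chromosome 1, 20297965 to 20300908, minus strand, TAIR10) was lower in all 3 mutant libraries. Its level was 16.0 ± 0.643 CPM in WT and 4.54 ± 0.0846 CPM in gemin2 (n = 3 each), a log2 fold change of -1.82 (SE 0.0968, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.46e-09). The counts were 239, 262 and 221 in WT against 71, 77 and 74 in gemin2. In the intron I003 of GEMIN2 (20299245 to 20300121), named after its values were seen, the reads were 27, 32 and 36 in WT and 18, 26 and 22 in gemin2. Relative to the gene this was 13.3 ± 2.66 against 29.6 ± 4.21 reads per 100 gene reads (adjusted p = 0.00568, edgeR with the gene count as offset). The intron's reads fell too, and the ratio rose because the gene's reads fell more. In the mutated gene itself this does not show more retention.

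Among the genes taken by the naming rule, which needs a symbol and a minimum level, the increases included genes of single defence peptides and the decreases several genes of the anthocyanin pathway. The plant defensins PDF1.3 (AT2G26010) and PDF1.2A (AT5G44420) rose by 4.45 (SE 0.444) and 4.19 (SE 0.601), the thionin THI2.2 (AT5G36910) rose from 13.3 ± 3.33 to 88.7 ± 0.979 CPM, and TASTY (AT1G54040), the epithiospecifier protein that directs glucosinolate breakdown, rose from 30.6 ± 2.24 to 188 ± 36.8 CPM. PAP1 (AT1G56650), the MYB activator of anthocyanin synthesis, changed by -2.62 (SE 0.264), with 94, 119 and 172 reads in WT and 25, 18 and 25 in gemin2. DFR (AT5G42800), a late enzyme of the pathway, went from 58.8 ± 13.2 to 13.3 ± 2.60 CPM, and TT19 (AT5G17220), a glutathione transferase needed for anthocyanin storage, from 32.8 ± 2.06 to 7.57 ± 1.71 CPM.

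Among the 20762 genes tested, 7626 passed an adjusted p of 0.05 (edgeR quasi-likelihood test), 3698 higher and 3928 lower in gemin2 (48.5% higher). The balance of the directions depends on the normalisation, which centres the fold changes. Most changes were small, with a median absolute log2 fold change of 0.36 among them. A change of at least 0.58 was found for 1884 genes (859 higher, 1025 lower) and of at least 1 for 648 genes (305 higher, 343 lower). The 2 genotypes did not overlap in 9993 of the tested genes (48.1%, against 10% by chance) and in 7354 of the genes called (96.4%). The first principal component held 64.7% of the variance and separated the genotypes.

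The other higher genes taken by the naming rule were AACT1 (AT5G61160), annotated as an anthocyanin acyltransferase, at 4.72 (SE 0.295), the patatin-type phospholipase PLA.IIA at 3.16, the receptor-like protein RLP33 at 2.68, the defence-responsive LURP1 at 2.57, the histone gene HTR11 at 2.55 and the potassium transporter HAK5 at 2.38. The other lower genes were the receptor kinase genes SRF4 at -2.49 and CRK28 at -1.87, the anthocyanin malonyltransferase 5MAT at -2.19, the vegetative storage protein VSP2 at -2.11, the glucosidase BGLU1 at -2.01, the bHLH regulator TT8 at -1.94 and the anthocyanin enzyme LDOX at -1.74. Adjusted p-values of these and of the genes named before them ranged from 1.68e-10 to 0.000114. SRF4 overlaps another annotated gene, and its reads cannot be told apart from that gene's here. Of the 10 WT reads of PDF1.3, 9 were in WT B, and without that library its log2 fold change was 6.85. Of the WT reads of PDF1.2A (2, 10 and 0), most were in WT B too, and without it the value was 5.98. The rule for reads that map to several places is not given. Reads shared between the defensin genes PDF1.3, PDF1.2A and PDF1.2B therefore cannot be excluded, and single ones are uncertain.

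**Figure D1:**
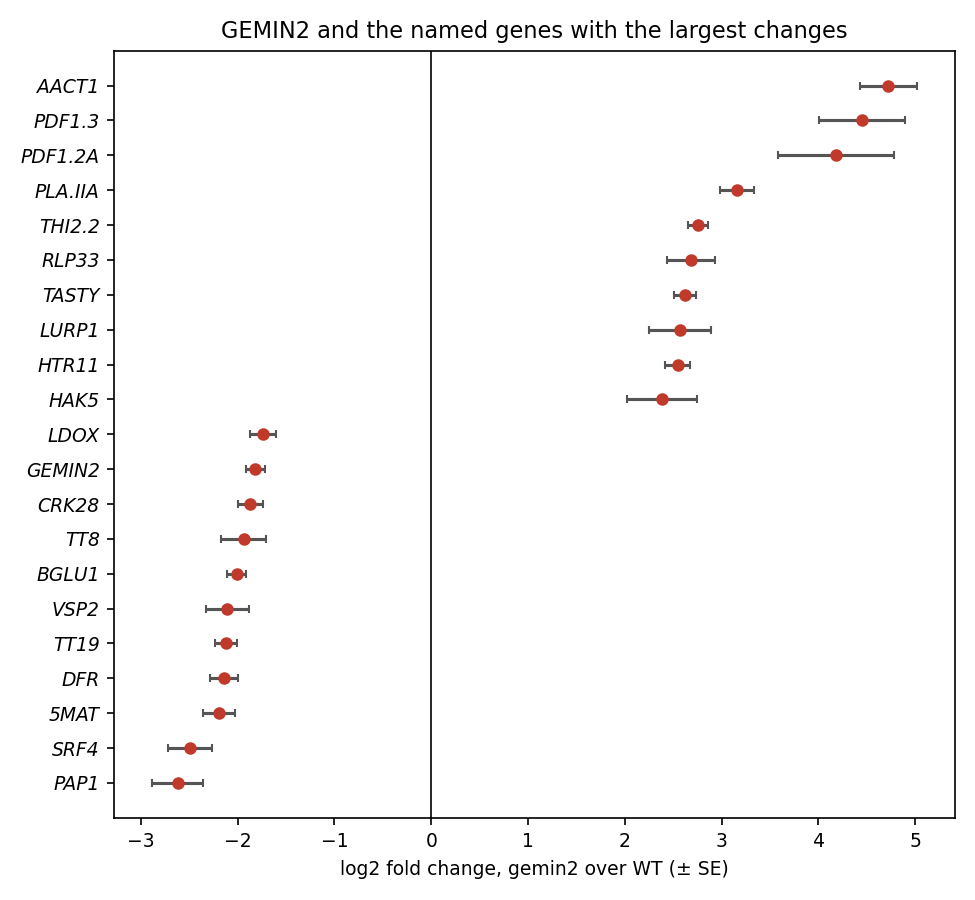
Log2 fold changes (gemin2 over WT, x axis) of GEMIN2 and of the named genes with the largest changes (y axis); points are estimates of the edgeR quasi-likelihood fit over 3 libraries per genotype and bars are ± SE. Values run from -2.62 for PAP1 to 4.72 for AACT1, and GEMIN2 lies at -1.82.

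All 13 tested members of the anthocyanin and flavonoid list fell (0 higher; 13 lower also when adjusted over the list alone). Besides PAP1, DFR and TT19, UF3GT changed by -1.58 and TT7 by -1.12, and the early enzymes CHS, CHI and F3H by -0.27, -0.18 and -0.31. Whether early and late steps differ was not tested. The camera test gave an adjusted p of 2.38e-10 for the list, and adjusted p = 0.304 with an estimated correlation. All 15 tested cold response genes rose (15 when adjusted over the list alone). KIN2 rose from 73.2 ± 5.48 to 206 ± 39.5 CPM, COR413IM1 by 1.14 (SE 0.0754), the dehydrin COR47 by 0.55, and the transcription factors CBF2 and CBF3 by 1.59 and 2.46. The gemin2 C library stood above the other mutant libraries in several of them, among them COR15A (728, 687 and 1540 reads in gemin2 A, B and C, against 469, 414 and 481 in WT) and RD29A (914, 1035 and 1625, against 446, 490 and 409). The list's adjusted p was 3.99e-10 (camera), adjusted p = 0.304 with an estimated correlation, and 4.78e-11 without gemin2 C.

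In the photosynthesis list, 16 of 22 members rose, 5 fell and 1 did not pass, with the same counts when adjusted over the list alone. The 16 that rose were its light-harvesting antenna genes, led by LHCB1.4, from 1025 ± 88.5 to 4007 ± 270 CPM (1.97, SE 0.0728), and LHCB1.5, from 3534 ± 239 to 8143 ± 25.2 CPM. The 5 that fell act in carbon fixation: RBCS2B at -0.74, RBCS1B at -0.65, RBCS3B at -0.42, the carbonic anhydrase CA1 at -0.64 and Rubisco activase RCA at -0.30. The Rubisco subunit gene RBCS1A was at -0.04 (adjusted p = 0.637, edgeR). The camera test gave an adjusted p of 8.76e-05, and adjusted p = 0.593 with an estimated correlation. Some members of the LHCB and RBCS families may be alike enough for the counting to split their reads, which was not measured here. LHCB1.5 also overlaps another gene. Single members of these families are therefore uncertain.

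Of 29 circadian clock genes, 15 rose, 6 fell and 8 did not pass (16 and 6 when adjusted over the list alone). The clock coactivator LNK2 rose by 0.90 (SE 0.0483), from 127 ± 0.932 to 238 ± 12.3 CPM, and GI by 0.87 (SE 0.0675). The MYB-like factor RVE2 changed by -1.10 (SE 0.0598) and the evening complex gene ELF3 by -0.41 (SE 0.0617). The adjusted p of the list was 0.00801 (camera), and adjusted p = 0.374 with an estimated correlation. LNK2 and ELF3 overlap other annotated genes. Light signalling genes rose in 7 of 14 cases with 0 lower (7 and 0 when adjusted over the list alone), among them PHYA by 0.44 and PIF5 by 0.60, with a camera adjusted p of 0.00964 and adjusted p = 0.304 with an estimated correlation. Of 17 dividing cell markers, 11 rose, 0 fell and 6 did not pass (12 and 0 when adjusted over the list alone). CYCD3;1 rose by 0.38 and the cytokinesis syntaxin KN by 0.40. The list's adjusted p was 0.000603 (camera), and adjusted p = 0.374 with an estimated correlation.

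Among 39 genes of Sm, LSm and other snRNP proteins, 11 rose, 1 fell and 27 did not pass (11 and 1 when adjusted over the list alone). The U5-associated factors STA1 and PRP8 rose by 0.61 (SE 0.0526) and 0.45 (SE 0.0491). U1-70K, a protein of the U1 snRNP, changed by -0.53 (SE 0.0541), from 86.0 ± 5.61 to 59.4 ± 0.933 CPM. With the reads of its retained-intron bin E005 taken off the gene count, an alternative chosen after seeing the data, U1-70K was at -0.16 (65.2 ± 2.87 against 58.4 ± 1.15 CPM, edgeR adjusted p = 0.0241), so if the deposited gene counts include that bin it made up most of the fall. The camera adjusted p was 0.0279, and adjusted p = 0.593 with an estimated correlation. Without WT B it was 0.0639 and without gemin2 B 0.0604. Of 20 SR splicing regulators, 4 rose, 5 fell and 11 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.550). SR34B rose by 0.39 and SR30 by 0.19, whereas RS31A changed by -0.62 and SCL33 by -0.37. The call of SR30 was lost without WT C (adjusted p = 0.0539, edgeR) and without gemin2 B (0.0645), and RS31A overlaps another gene.

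Of 19 tested flowering time genes, 6 rose, 7 fell and 6 did not pass (7 and 8 when adjusted over the list alone, camera adjusted p = 0.882). The floral repressor FLC changed by -2.91 (SE 0.336), from 2.81 ± 0.773 to 0.371 ± 0.139 CPM, and AGL24 by -1.56. FLK, an RNA-binding protein that represses FLC, rose by 0.80 (SE 0.0509) and SVP by 0.40. FLC was not among the largest decreases taken by the naming rule because its mean log2 CPM, 0.75, lay under 1.

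Jasmonate genes moved both ways, with 4 of 15 higher, 4 lower and 7 not past the threshold, and the same counts when adjusted over the list alone. PDF1.2B had 3 WT reads against 86 in gemin2, a ratio of 26.4 (95% counting interval 8.75 to 131; its fitted value moved from 4.57 to 5.34 without WT B), and AOC2, an enzyme of jasmonate synthesis, rose by 0.94, whereas the storage protein genes VSP2 and VSP1 changed by -2.11 and -1.48. The list's median was -0.07, its mean 0.39 and its camera direction downward, so these differed in sign (adjusted p = 0.945). Of 16 salicylic acid and defence genes, 4 rose, 0 fell and 12 did not pass (2 and 0 when adjusted over the list alone, camera adjusted p = 0.252). PR1 was at 1.70 (SE 0.503, adjusted p = 0.0154) and ICS1 at 0.24 (SE 0.0722, adjusted p = 0.0187) by edgeR. Both calls were lost with DESeq2 (0.199 and 0.156). WT B held 18 of the 21 WT reads of PR1, whose value was 3.74 without that library, and its call was lost without WT A (0.0600) and without WT C (0.0731), that of ICS1 without WT B (0.0815).

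Abscisic acid and drought genes gave 3 higher, 3 lower and 10 not past the threshold among 16 (4 and 4 when adjusted over the list alone, camera adjusted p = 0.929). ABF3 rose by 0.53 and HAI1 by 0.66, the latter 0.40 without gemin2 C (adjusted p = 0.0425), whereas RD20 went from 15.8 ± 2.12 to 7.92 ± 3.47 CPM and RD26 was at -0.57. RD20 did not pass with a robust fit (adjusted p = 0.0760). The list's median was 0.06 and its camera direction upward, whereas its mean was -0.09. Of 10 heat response genes, HSP90.1 (0.57) and HSP70 (0.42) rose and 8 did not pass (2 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.252). Of 19 root organ markers, 3 rose, 4 fell and 12 did not pass (5 and 6 when adjusted over the list alone, camera adjusted p = 0.472). SCR and PHO1 were at 0.21 and 0.24, PHO1 losing its call without gemin2 B (adjusted p = 0.0602, edgeR), and the iron transporter IRT1 and the root hair regulator RHD6 changed by -0.68 and -1.07. Of 12 aliphatic glucosinolate genes, 4 rose, 2 fell and 6 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.534). The regulators MYB29 and MYB28 rose by 0.56 and 0.28, whereas BAT5 and BCAT4 changed by -0.33 and -0.32, BCAT4 overlapping another gene. Only 2 of 10 seed storage genes were tested, and neither passed: OLEO2 was at 0.48 (adjusted p = 0.381) and CRA1 at 0.32 (adjusted p = 0.763), with unadjusted p-values of 0.253 and 0.663 by edgeR. Without 1 library OLEO2 ranged from 0.09 (without WT A) to 0.80 (without WT C), and CRA1 passed at 2.79 without WT B (0.0224) and turned to -0.18 without WT A, -0.10 without WT C and -0.10 without gemin2 A.

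**Figure D2:**
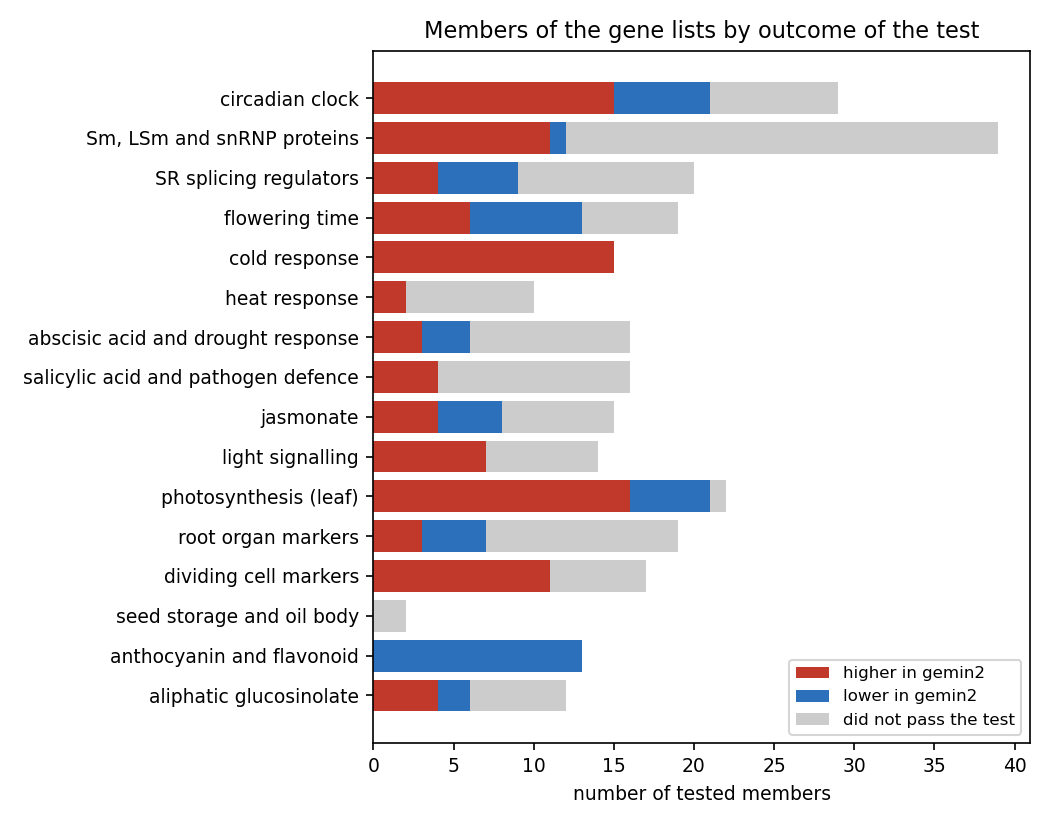
Number of tested members of each gene list (x axis) that were higher in gemin2, lower in gemin2 or did not pass the edgeR test, by list (y axis). All 15 cold response genes were higher and all 13 anthocyanin and flavonoid genes lower.

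Reads of rRNA loci made up 0.461%, 0.264% and 0.230% of gene reads in WT A, B and C and 0.640%, 0.551% and 0.787% in gemin2 A, B and C. Reads of organelle loci made up 0.480%, 0.205% and 0.182% in WT and 0.584%, 0.540% and 0.815% in gemin2. Both shares were higher in each mutant library than in any WT library. With these loci left out, an alternative chosen after seeing the data, 7643 genes passed.

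Relative to their genes, single introns rose in some genes and fell in others. The intron I001 of TASTY (chromosome 1, 20171988 to 20173852, minus strand) rose from 2.45 ± 0.933 to 32.7 ± 0.440 reads per 100 gene reads (log2 change 3.75, SE 0.168, adjusted p = 1.57e-08, edgeR with the gene count as offset). The introns CP5 I001, RPL4 I002, ACA4 I001 and PSAE-2 I002 rose by 3.02, 2.50, 3.55 and 2.55. In the clock gene CCA1 the intron bins I004 (chromosome 2, 19246385 to 19246751, plus strand) and I005 (19246752 to 19246862) fell. They went from 5.55 ± 0.536 to 1.76 ± 0.341 and from 2.57 ± 0.619 to 0.508 ± 0.138 reads per 100 gene reads. These bins abut with no exon between them, so they are parts of the same stretch and not independent.

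In all, 464 of 4938 tested introns passed (edgeR quasi-likelihood test, adjusted p under 0.05), 293 higher and 171 lower (63.1% higher, binomial p = 1.61e-08, which treats introns as independent), in 413 of 3261 genes. With a minimum count of 20, 209 introns passed and 112 of them (53.6%) were higher, a share near even that was not tested. The excess of higher introns thus depended on the filter for low counts. Of the introns with an adjusted p under 0.01, 75.3% were higher, and of the 118 past 0.05 with DESeq2, 81.4%. A change of at least 1 was found for 262 higher and 129 lower introns. With no gene offset, 684 introns passed, 50.4% of them higher. Of the 464, 20 overlap another annotated gene. The other introns taken by the naming rule were higher in genes of chloroplast and photosynthesis proteins, CA1 I010 at 1.83 and I002 at 0.74, LHCA2 I002 at 2.04, and MORF9 I003 with 2 WT reads against 161 (ratio 71.7, 95% counting interval 19.5 to 597), and in ATDI19 I001 at 1.43. CA1 I002 did not pass without the gene offset (adjusted p = 0.487) or with DESeq2 (0.311). EMB3103 I009 fell, with 84 WT reads against 2 (a ratio of 34.7, WT over gemin2, interval 9.30 to 291), both of them in gemin2 A, without which its fitted value moved from -4.90 to -7.72. LpxC2 I003 at -0.83 and LpxC3 I003 at -0.22 lie in near-identical copies, overlap another gene and did not pass with DESeq2 (0.195 and 0.986), and LpxC3 I003 did not pass with the exact test either (0.661), so both are uncertain. LpxC3 I003 had more reads than its gene (192 ± 3.92 and 165 ± 2.72 reads per 100 gene reads), so that gene's count cannot include all of its intron reads.

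Among introns of the circadian clock list, 2 of the 16 tested rose and 5 fell, in 5 of 9 genes. GRP7 I002 rose from 10.2 ± 0.755 to 16.0 ± 0.175 and ELF3 I002 fell from 18.0 ± 1.87 to 10.4 ± 0.293 reads per 100 gene reads. PRR9 I007 had 2 WT reads against 39 (ratio 13.6, 95% counting interval 3.52 to 116). CCA1 I004 and I005, which abut and count as 2 of the 5, were both lower, and RVE8 I009 and I004 were at -0.99 and -0.89. With DESeq2, adjusted p was 0.457 for GRP7 I002, 0.329 for ELF3 I002 and 0.0501 for PRR9 I007, and for PRR9 I007 it was 0.0997 with limma-voom. RVE8 I009 and I004 gave 0.416 and 0.558 with DESeq2, and I004 gave 0.0534 with limma-voom, 0.0599 without the gene offset and 0.136 without a filter. The RVE8 calls were the weakest: I009 (adjusted p = 0.0326, edgeR) was kept without WT B or gemin2 A and lost without WT A (0.112), WT C (0.0813), gemin2 B (0.123) or gemin2 C (0.0532), and I004 (0.0442) was lost without any 1 library (0.0605 to 0.145).

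Introns of the SR list rose in 3 cases and fell in 4 of the 16 tested. SR30 I011 had 1 WT read against 36 (ratio 29.1, 95% counting interval 4.89 to 1179), SCL30 I007 had 3 against 37 (ratio 13.6, 4.30 to 68.8) and SR34 I001 had 0 against 23, at least 7.23-fold higher. SCL33 I003 fell from 20.3 ± 1.44 to 12.2 ± 1.58 reads per 100 gene reads, and SCL33 I005, SR45 I001 and RS31A I004 were at -1.01, -1.78 and -1.78. For the Sm, LSm and snRNP list, 1 of 15 introns rose and 3 fell: AT3G07590 I002, in a gene annotated as an Sm protein, was at -2.07, PRP39 I011 and I007 at -0.91 and -1.63, and LSM3A I002 at 0.98. Of these 11 introns, SCL30 I007 (0.0503), RS31A I004 (0.191), PRP39 I007 (0.0676) and LSM3A I002 (0.0828) missed the threshold with limma-voom, and all that were lower, as well as LSM3A I002, missed it with DESeq2 (0.117 for AT3G07590 I002 to 0.491 for LSM3A I002). AT3G07590 I002 also missed it without the gene offset (0.0514), RS31A I004 (0.0844) and LSM3A I002 (0.0528) without a filter, and LSM3A I002 with the exact test (0.0523). Without WT A the fitted values of SR30 I011 and SCL30 I007 rose to 6.49 and 4.50, and the calls of SR45 I001 (0.0502), SCL33 I005 (0.0646), RS31A I004 (0.119), PRP39 I011 (0.0660) and I007 (0.101) and LSM3A I002 (0.0655) were lost, as were those of PRP39 I011 without WT B (0.0741) or gemin2 C (0.0715). RS31A I004 was kept only without WT C, PRP39 I007 only without gemin2 A and LSM3A I002 only without gemin2 A, with highest adjusted p-values of 0.119, 0.128 and 0.191 over the fits without 1 library.

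The shift of the median intron was small, and the libraries are too few for its test to pass 0.05. The median log2 ratio of intron to gene reads was 0.0504 ± 0.0384 in WT and 0.0300 ± 0.00480 in gemin2, a shift of -0.0204 over 4938 introns (n = 3 each, exact permutation p = 0.7, two-sided, where the smallest possible is 0.1). WT A (0.0947) stood above the other 5 libraries (0.0246 to 0.0339), and without it the shift was 0.0199. With 1 intron per gene it was -0.0387, and both of these had an exact permutation p of 0.1, the smallest possible, with opposite signs.

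Annotated splicing bins changed in both directions, and the bins with the smallest p in each direction were retained introns. The intron retention bin E005 of U1-70K (AT3G50670, chromosome 3, 18827440 to 18828348, minus strand, 909 bp) fell from 24.0 ± 1.67 to 1.77 ± 0.394 reads per 100 gene reads (log2 change -3.77, SE 0.137, adjusted p = 5.42e-23, edgeR with the gene count as offset). Its reads were 303, 299 and 324 in WT and 19, 14 and 18 in gemin2. Whether the gene counts include such reads is not given in the sources used here. Intron retention bins rose in RPT2 (E005, the phototropin partner protein, from 0.272 ± 0.0442 to 3.46 ± 0.123 reads per 100 gene reads), in the ribosomal protein gene RPS5A (E005, from 0.576 ± 0.168 to 4.24 ± 0.203) and in ATBBD1 (E002, from 0.166 ± 0.0439 to 2.94 ± 0.103).

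Of 4649 bins tested, 219 passed (edgeR quasi-likelihood test), 121 higher and 98 lower (55.3% higher, binomial p = 0.137), in 200 of 3313 genes, and 85 higher and 49 lower bins changed by at least 1. With no gene offset 689 passed, 42.8% of them higher. Of 1277 intron retention bins 60 were higher and 34 lower. They changed more often than the other types pooled (odds ratio 2.06, 95% interval 1.55 to 2.74, Fisher's exact p = 5.31e-07), but in a share (7.36%) close to that of exon skipping bins (6.82%) and of bins of several types (6.56%), and above that of alternative 5' (3.61%) and 3' site bins (1.35%). The changed ones were more often higher than those of the other types pooled (odds ratio 1.85, 1.03 to 3.33, Fisher's exact p = 0.0289), although not than alternative 5' site bins. Alternative 5' site bins were higher in 21 and lower in 4 of 692 cases, alternative 3' site bins higher in 6 and lower in 14 of 1478, exon skipping bins higher in 9 and lower in 20 of 425, and bins of several types higher in 25 and lower in 26 of 777. Directions are those of a bin's own reads, so a lower exon skipping bin means fewer reads of that exon, not less skipping. The retention bins RPL4 E003, ERD15 E006 and iPGAM2 E010 rose by 2.46, 2.40 and 3.54, and the aquaporin gene PIP1;2 had 2 higher bins, E005 at 2.24 and E004 at 2.50. The PIP1;2 bins abut, as do RPL4 E003 and the intron RPL4 I002, so neither pair is independent. The alternative 5' site bin OBE2 E004 had 2 WT reads against 109 (ratio 43.4, 95% counting interval 11.7 to 363), both in WT B, without which its fitted value moved from 5.22 to 8.04. Of the 219 bins, 6 overlap another gene and 3 lie in loci whose counts are identical to another locus.

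**Figure D3:**
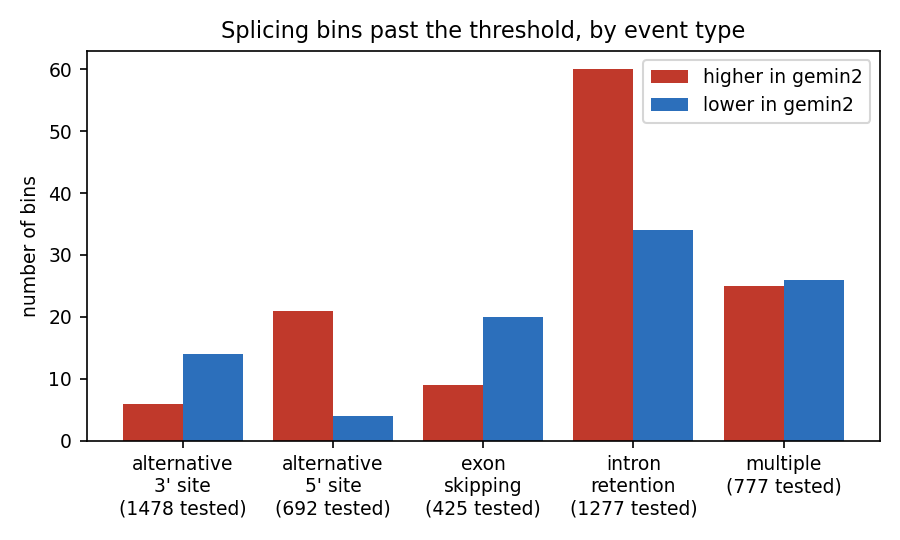
Number of annotated splicing bins past an adjusted p of 0.05 (y axis) whose own reads were higher or lower in gemin2 relative to their gene, by event type with the number tested (x axis). Intron retention bins were higher in 60 and lower in 34 cases, and alternative 5' site bins higher in 21 and lower in 4.

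Lower bins taken by the naming rule were RLM3 E010 at -1.33, CHLM E007 and E008 at -0.69 and -0.61 and RCA E002 at -1.79. The CHLM bins abut, so they are not independent. In RCA, E003 was higher by 0.26 (SE 0.0265). The RCA E002 reads in WT B, 1113, stood above those in WT A (300) and WT C (320), and without WT B the value was -1.03. RCA E002 did not pass with DESeq2 (adjusted p = 0.0716), and RCA E003 (-0.04, 0.792) and CHLM E008 (0.0878) did not pass without the gene offset. In the clock list 1 of 23 bins rose, LNK2 E013 by 1.36, and 0 fell. In the Sm, LSm and snRNP list 0 of 18 rose and 3 fell, U1-70K E005 and the exon skipping bins PRP39 E009 and E010 at -1.11 and -1.16. In the SR list 0 of 22 rose and 2 were lower, SR30 E003 at -0.35 and RS41 E004 at -0.53 (adjusted p = 0.00779 and 0.0469, edgeR). SR30 E003 was lost without WT A (0.124), with DESeq2 (0.177) and without the gene offset (0.394), and RS41 E004 with DESeq2 (0.672), limma-voom (0.0506), the exact test (0.0583), no filter (0.0565) and without any 1 library (0.0600 to 0.307).

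**Figure D4:**
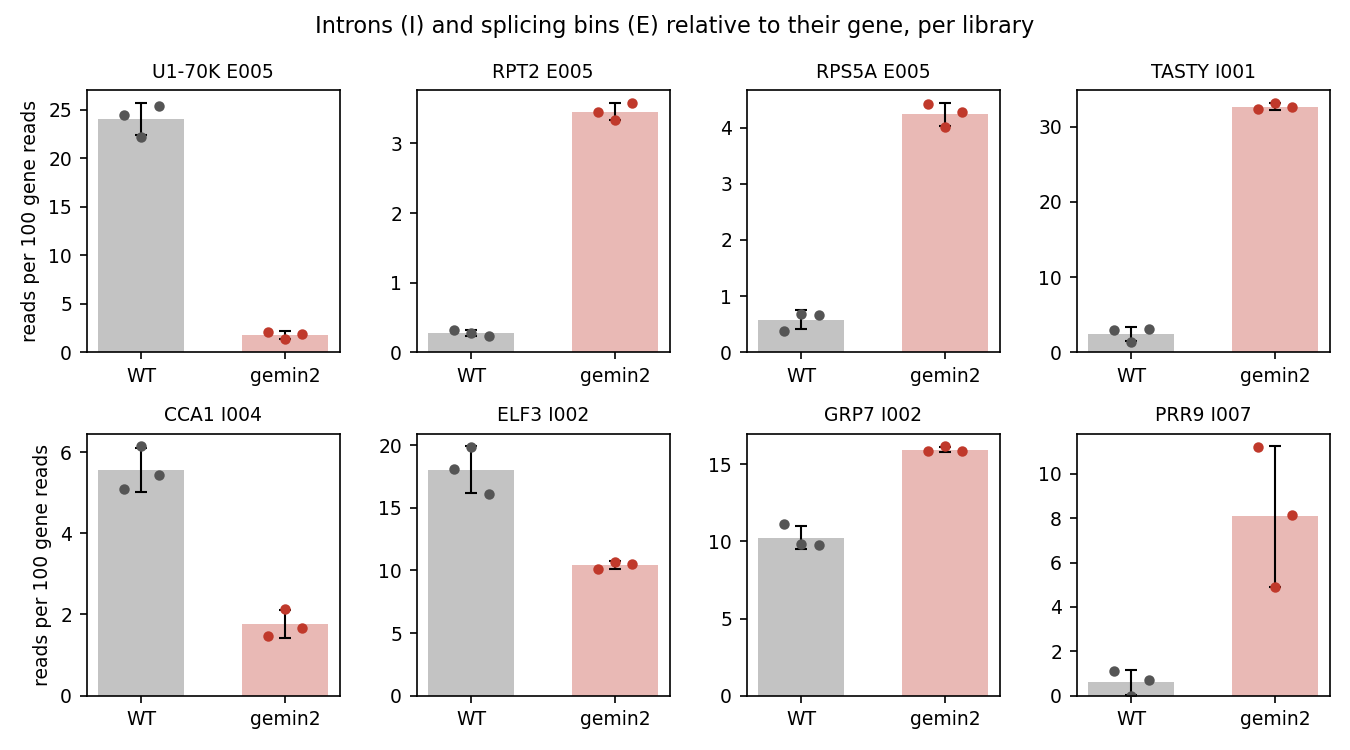
Reads per 100 gene reads (y axes, each from 0) of 8 named introns (I) and splicing bins (E) in WT and gemin2 (x axes); points are libraries, bars are means of 3 libraries and error bars SD. U1-70K E005 falls from 24.0 to 1.77 and TASTY I001 rises from 2.45 to 32.7.

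Genes with a changed intron were more often changed in level. Among the 3261 genes tested for both, 237 of the 413 with a changed intron had a changed level (57.4%, against 44.7% of the others), an odds ratio of 1.67 (95% interval 1.35 to 2.07, Fisher's exact p = 1.44e-06, two-sided). Of these 237 genes, among them TASTY, CA1, LHCA2, ELF3, CCA1 and SCL33, 91 were higher and 146 lower in level. For splicing bins, 110 of 200 genes with a changed bin had a changed level (55.0%, against 42.8% of the others; odds ratio 1.64, 1.22 to 2.21, Fisher's exact p = 0.000892), U1-70K, RCA, LNK2 and SR30 among them. Both tests share the gene counts that serve as offset of the splicing tests. The genes were not matched on read depth, which affects the calls of level and of splicing, so depth may contribute to both odds ratios.

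The authors' deposited table of genes lists 1226 loci, 553 higher and 673 lower, with adjusted p-values up to 0.0471 and absolute log2 fold changes from 0.59, and gives GEMIN2 -1.82 (adjusted p = 1.14e-59). Of 1223 of these tested here, 1219 passed the edgeR test, where independent lists would share 492, and the 1219 had the same direction. The authors' deposited table of splicing events lists 321 bins, 172 higher and 149 lower, 122 of them intron retention (67 higher) and 40 alternative 5' site (33 higher), with adjusted p-values up to 0.102 and so past the 0.05 used here. Of 294 tested here, 160 passed, all in the same direction (14.4 for independent lists). The authors' deposited table of introns lists 1349, 880 higher and 469 lower, 488 of them on chromosomes 4 and 5, which were not analysed here, with adjusted p-values up to 0.105. Of 602 tested here, 355 passed in the same direction (58.7 for independent lists). The authors' deposited tables rest on the same counts as the values here.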

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

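The alternatives with the column letter as a block, with the reads of bin E005 taken off the gene count of U1-70K, with loci of identical counts left out, and with rRNA and organelle loci left out were chosen after seeing the data, and the others before. Leaving out loci of identical counts gave 7556 genes, 467 introns and 215 splicing bins, and leaving out rRNA and organelle loci 7643 genes.

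The number of changed genes (7626) was 5128 with DESeq2, 5042 of them shared, and between 7090 and 7894 with RLE normalisation, limma-voom, edgeR's exact test, a robust fit, a minimum of 50 or no filter. It was 1884 with a minimum absolute log2 fold change of 0.58 and 4958 at an adjusted p under 0.01, both by construction, and 6281 to 6817 without 1 library. Under each of these fits, the genes shared with the original call had the same direction. The number of changed introns (464) was 118 with DESeq2 (all 118 shared, 81.4% higher), 292 with limma-voom (290 shared, 61.0% higher), 209 with a minimum count of 20 (180 shared, 53.6% higher against 63.1%), 223 at an adjusted p under 0.01 (75.3% higher) and 322 to 352 without 1 library. For splicing bins (219) it was 84 with DESeq2 (all shared, 63.1% higher), 142 with a minimum count of 20 (51.4% higher), 143 at an adjusted p under 0.01 (60.1% higher) and 155 to 194 without 1 library. With no gene offset, 684 introns and 689 bins passed, since a change of the whole gene then counts as well. Under that setting RCA E003 turned from 0.26 to -0.0354 (adjusted p = 0.792), RCA itself being lower in gemin2. The cause of the lower counts with DESeq2 was not tested.

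With an estimated correlation between genes, the camera test of 7 lists no longer passed: circadian clock 0.374, Sm, LSm and snRNP proteins 0.593, cold response 0.304, light signalling 0.304, photosynthesis 0.593, dividing cell markers 0.374 and anthocyanin and flavonoid 0.304. The directions were the same. Only the correlation setting differed: its estimates for these lists ran from 0.0280 (light signalling) to 0.525 (photosynthesis), against the preset 0.01. Without 1 library the Sm, LSm and snRNP list ranged from 0.00834 to 0.0639, passing neither without WT B (0.0639) nor without gemin2 B (0.0604). The cause of the changes without 1 library was not tested.

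The median intron shift (-0.0204) ranged from -0.0664 to 0.0199 without 1 library, the highest without WT A, and was -0.0664 without gemin2 B and -0.0622 without gemin2 C. The odds ratio between changed introns and changed genes (1.67) was 2.31 at an adjusted p under 0.01, 1.64 with a gene mean of at least 100 and 1.72 to 2.16 without 1 library.

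The letters of the columns did not pair the libraries: deviations of WT and gemin2 libraries of the same letter correlated at -0.00555 (A), -0.0156 (B) and -0.0578 (C). With the letter as a block, 7512 genes, 374 introns and 201 bins passed, the odds ratio was 1.76, and the calls of RVE8 I004 (0.0596), PRP39 I007 (0.0579), LSM3A I002 (0.0723) and RS41 E004 (0.0579) were lost.

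Of the named genes, 61 of 67 kept their side of the threshold and direction under every alternative fit run for them, and of the named introns and bins 29 of 51. The stricter thresholds (adjusted p under 0.01 and a minimum log2 fold change of 0.58) were not applied to named items. In simulated counts 26.9% of introns and 64.2% of bins changed 2-fold were recovered, against 94.0% of genes, so splicing changes of that size were more often missed. Depth was not varied, and the simulations of introns and bins also differed in dispersion.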

Other observations

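The tests of the introns that were lower, of GC content, of intron length, of windows and of runs of genes were chosen only after the results were seen, as were the genes named in this part. The other tests were written down before they were run, although the nearness of some strongly changed genes to each other, and of TASTY to GEMIN2, had by then been noticed.

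The strongest decrease in the comparison was in a gene with no symbol, which the naming rule left out. AT3G01345 (chromosome 3, 129138 to 130749, plus strand), an uncharacterized protein, had 3730, 4489 and 3921 reads in WT and 13, 9 and 6 in gemin2, a log2 fold change of -8.86 (SE 0.106, edgeR adjusted p = 3.28e-17). AT5G27250 had 57, 82 and 82 reads against 2, 2 and 4 (-4.84), AT4G13575 changed by -3.17, AT4G17470, a hydrolase, by -2.94 and AT1G31690, a copper amine oxidase, by -2.39. AT3G23550, a MATE efflux protein, rose by 2.89 and AT1G15405 by 3.21.

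Of the 10 splits of the 6 libraries into groups of 3, only 1, the real one, gave as many changed genes (7626, highest other 0), as many changed introns (464, highest other 4) and as many changed splicing bins (219, highest other 1). With 10 splits the share cannot fall under 0.1, which is too few for a test.

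Genes changed by at least 1 on the log2 scale lay next to each other in 65 pairs of neighbours, against 19.5 when shuffled (p = 1e-05, the smallest that 100000 permutations can give). AT4G13575 belongs to a run of 4 lower genes with UNE15, HTA4 and AT4G13572 (chromosome 4, 7879561 to 7893705). Other runs included AT4G22212 to AT4G22235 (4 lower), AT2G11270 to AT2G11310 (4 higher), the transporters ATPDR2, ABCG42 and ABCG43 (3 higher), and AT2G01008 to AT2G01021 (4 higher) and AT3G41762 to AT3G41979 (3 higher), which hold the rRNA loci whose share of the reads was higher in gemin2. Runs of mixed direction were AT2G04039 to AT2G04070, AT2G25980 to PDF1.2B and LHCB1.5 to AGL29 (each 2 higher, 1 lower), and AT5G54040 to U3D (2 higher, 2 lower). Between the genes of a run, 1 tested gene without such a change was allowed. Windows starting at 7500001 on chromosome 4 (11 of 91 genes, adjusted p = 0.0255) and at 4000001 on chromosome 2 (4 of 12, adjusted p = 0.0426) held more such genes than the genome (hypergeometric test). The run of AT4G13575 and that of AT2G11270 to AT2G11310 lie in or overlap these windows. The windows are thus not separate observations, and their test treats neighbouring genes as independent. Sequence linked to the GEMIN2 locus was tested as a source: within 2 Mb of it 20 of 702 genes (2.85%) were so changed against 3.08% elsewhere (odds ratio 0.923, 95% interval 0.556 to 1.45, circular-shift permutation p = 0.572, one-sided), which argues against it for the pattern as a whole. TASTY, 127 kb from GEMIN2, is a single gene that this test does not decide. Without overlapping genes and identical copies 44 pairs remained against 15.6 (p = 1e-05), and without pairs of the same product 51 against 18.7 (p = 1e-05), both the smallest the permutations can give. Overlapping genes and identical copies thus do not account for the whole excess. Genes annotated as hypothetical, uncharacterized or transmembrane proteins, or with no product, were never counted as having the same product. Tandem relatives among them could not be left out, so the product test does not decide that explanation. Sequence differences between the lines away from GEMIN2 may add to the excess and were not tested.

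Weak 5' splice sites were tested as a reason for higher introns in gemin2, and the opposite was seen. The median score was 7.08 bits in 285 higher introns and 6.65 bits in 4317 that did not pass (matched permutation p = 0.0212, adjusted p = 0.0296). Matching on length, gene level and intron level kept 83.8% of the difference, and without introns that overlap another gene it was 0.340 bits (permutation p = 0.0320). The levels were means over all 6 libraries, which include the mutant reads that define the higher introns. Levels in WT alone were not matched, so the test does not decide whether they explain the difference. The rule that reads the matched share was changed after its result was seen, to follow the bound written beforehand. The lower introns scored higher still (7.50 bits, permutation p = 0.00293), and the matching was coarse, so a selection among tested introns may explain part of it. Higher introns were richer in GC (34.9% against 33.5%, p = 1e-05, the smallest the permutations can give) and shorter (99 bp against 167 bp, p = 0.00108), and lower introns longer (266 bp, p = 0.00223). For the higher introns, none of the tested positions of the 5' site passed after adjustment (lowest adjusted p = 0.478, Fisher's exact test), and the lower introns were not tested by position.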
